A study of Mus musculus with 13 samples.

How the data were processed

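The series holds 13 libraries of mouse RNA, 6 from E0771 mammary tumours (3 in WT hosts, 3 in KO hosts) and 7 from visceral fat (3 WT, 4 KO). Per the labels' protocols, RNA was harvested with Trizol and about 500 ng went into each library, made with the Illumina TruSeq stranded mRNA kit. Groups were taken from the sample titles. In the deposited fat table the WT columns are numbered 1, 3 and 4 while the labels number the WT replicates 1, 2 and 3, so WT fat columns were assigned to the WT group only and are named by their column number.

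For the tumours, the authors deposited a read count per gene symbol with no normalisation, and per the submitters' processing notes CASAVA, TopHat, DESeq2 and the mouse genome build mm10 were used, with no versions, roles or parameters. The tumour count table ends in 5 summary lines that name no gene and stayed out of library sizes and tests. They held 66.7% to 72.2% of all entries per library. Alignments at several places alone made up 59.1% to 63.8% of all entries, and reads outside any gene 17.2% to 19.9% of those placed once in KO hosts and 20.4% to 22.7% in WT hosts. The tumour counts carry spreadsheet dates in place of 25 symbols of the March and Sept families. For fat, the deposited values are a signal per gene, read counts divided by 1 size factor per library, since the values of each column are whole multiples of its smallest value above 0. Of 117220 values above 0, 117220 came out whole within 0.001 (100%), with steps of 0.8603 to 1.104 per read. The labels do not state the counting tool, the annotation or the strand setting. Reads of overlapping or antisense genes, and of near-identical families (tryptases, serpins, guanylate-binding proteins, Hspa1a and Hspa1b, Ear and Orm genes), may therefore be divided between genes in a way that cannot be checked.

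All 22609 genes of each table were considered. Tumour counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, quasi-likelihood test), which left 13109 genes. Normalised tumour reads in the text are counts rescaled by TMM library size. Fat values were tested with limma 3.58.1 with trend on log2(value + 1), for genes with a value of 10 or more in at least 3 libraries, which left 14455 genes. Fold changes in fat are differences of group means on that scale, so they can differ from the ratio of the mean values and understate the change of low genes. Tests were two-sided, the difference was KO minus WT, and p values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The comparisons, tests, 40 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Lists with 5 or more tested members, 34 in the tumours and 35 in fat, were tested with camera at a preset correlation of 0.01, with a correlation estimated for each list, and with fry. A list score is the mean log2 difference of a library from the WT mean over the tested members, and its exact permutation test used 20 relabellings in the tumours and 35 in fat.

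The rule named, in each tissue, Cd274, then up to 10 largest rises and 10 largest falls among genes that passed, did not overlap between groups and had a mean of 50 or more, leaving out predicted gene models. Where no gene passed, it named the 5 of smallest p in each direction. It added the members of smallest p of each list, limited to 30 genes, and 10 genes per tissue fixed by name. It gave 46 genes in the tumours and 57 in fat, and the results of some of them are not reported here. Adgre1, fixed by name for fat, is in the table under its older symbol Emr1. Coordinates are those of GENCODE M21 on GRCm38, the assembly of mm10, matched by symbol for 45 and 55 of these genes. The effects of both tissues were compared by Spearman's rho over genes and by exact permutation of host labels within each tissue (700 relabellings).

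The pipelines were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed 2-fold or 4-fold. edgeR recovered 81% of 2-fold and 98% of 4-fold changes in simulated tumours (13127 genes, 5.82% of calls false), and limma 53% and 95% in simulated fat (14658 genes, 9.76% of calls false). DESeq2 recovered 85% and 98% in simulated tumours (16290 genes, 11.6% of calls false), and edgeR on recovered reads 53% and 94% in simulated fat (14661 genes, 12% of calls false). A list raised on purpose was called in each tissue and no unrelated list was. The simulated genes were drawn independently of each other, so this cannot show how often unrelated lists of correlated genes are called. The recovered shares hold for the simulated spread with 200 changed genes and are not the power in the real libraries. In the real tumours Cpa3, Tpsb2 and Tpsab1, at folds of 5.57 to 6.42, did not pass edgeR (adjusted p = 0.204). Libraries of a group were compared pair by pair for duplicates: the chi-square per degree of freedom ran from 24.2 to 58.5 over 6 tumour pairs and from 32.8 to 235 over 9 fat pairs, and 1 is the value of repeated sequencing of the same library.

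Alternatives were other normalisations (DESeq2 size factors, upper quartile, TMM rescaling, quantile), other pseudocounts and filters, DESeq2 1.42.0, limma without trend, the replicate number as a block in the tumours, and each library left out in turn. The test of edgeR on the recovered fat reads was chosen after seeing the data. It called 2356 genes higher and 2542 lower in fat, of which 4777 were also called by limma with the same sign. Rescaling the fat values moved the median log2 fold change by 0.0061 with TMM and -0.0114 with quantile normalisation. The 5 lists without 5 tested members in fat, and the 6 in the tumours, gave no test.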

Results

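RNA was sequenced from 2 mouse tissues of the C57BL/6 strain, each from wild-type (WT) hosts and from hosts labelled as lacking PD-L1 in fat (KO). PD-L1, the product of Cd274, is a surface ligand that restrains T cells through the receptor PD-1, encoded by Pdcd1. The first tissue was the E0771 mammary tumour, a transplantable mouse breast cancer line, with 3 tumours from WT hosts and 3 from KO hosts. The other was visceral fat taken after HFD (high-fat diet) feeding, with 3 WT and 4 KO libraries. The 6 tumour libraries held 22834259 to 34706555 reads assigned to genes, and the 7 fat libraries 29362788 to 41534662 recovered gene reads. The labels name replicates without saying that each came from its own animal, so the p-values measure the spread between these libraries. The question was what loss of PD-L1 in fat does to the transcriptome of visceral fat and to that of tumours in hosts with the KO label.

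Cd274, the targeted gene (chromosome 19, 29367455 to 29388095 on the plus strand of GRCm38), was not lower in the fat labelled KO. Its normalised value averaged 543.9 ± 17.6 (SD, n = 4) in fat labelled KO and 590.2 ± 129 (SD, n = 3) in WT fat, and the KO values of 521.1 to 563.8 lay inside the WT range of 504.1 to 738.6. The log2 fold change, KO minus WT, was -0.10 (SE 0.15), with a 95% confidence interval for the fold of 0.732 to 1.19. The adjusted p of limma was 0.66 and the two-sided exact permutation p over 35 relabellings was 0.8. In the tumours, where the hosts' fat and not the tumour cells carried the targeting, Cd274 averaged 2043 ± 432 (SD, n = 3) normalised reads in KO hosts and 1584 ± 167 (SD, n = 3) in WT hosts, a log2 fold change of 0.37 (SE 0.16). The adjusted p of edgeR was 0.717, and the exact permutation p was 0.3 where 3 libraries against 3 cannot go below 0.1. The values are sums over the whole gene in whole tissue, so they cannot show whether an exon was removed in adipocytes. Every direction below therefore rests on the labels, and KO stands for libraries labelled KO throughout.

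In visceral fat, genes of macrophages were higher and genes of fat cells and of the vessel wall were lower in the KO libraries. Itgax, which encodes the integrin CD11c of macrophages and dendritic cells, averaged 21480 ± 2450 (SD, n = 4) in KO and 2783 ± 1780 (SD, n = 3) in WT, a log2 fold change of 3.13 (SE 0.35). Adipoq, which encodes the adipocyte hormone adiponectin, averaged 26770 ± 5870 in KO and 114700 ± 13500 in WT, a log2 fold change of -2.12 (SE 0.24). Of 14455 genes tested with limma, 2430 rose and 2517 fell at an adjusted p under 0.05, and 1215 of the rises and 1142 of the falls were at least 2-fold. Fold changes in fat compare means of log2(value + 1), so they can differ from the ratio of the printed means, and this scale understates the change of low genes.

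Lipid-associated macrophages, cells that take up lipid in obese fat, were represented by 15 genes, of which 13 rose, 1 fell and 1 did not pass. Trem2, the lipid-sensing receptor of these cells, rose with a log2 fold change of 3.55 (SE 0.52, adjusted p = 0.00211), from 1803 ± 1720 in WT to 16180 ± 3780 in KO. Cd9, a tetraspanin of the same cells, rose 4.3-fold (log2 SE 0.21, adjusted p = 0.000939). The list as a whole was higher by a mean of 2.41 on the log2 scale (camera adjusted p = 4.33e-06), while the adjusted p was 0.805 with an estimated correlation. Adjusted over the list alone, 14 members rose and 1 fell.

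The broader macrophage list had 22 tested members, of which 17 rose, none fell and 5 did not pass. Emr1, the older symbol used in the file for Adgre1 and the gene of the macrophage marker F4/80, rose 6.32-fold (log2 SE 0.41, adjusted p = 0.00244). Ms4a7 rose 8.43-fold and the lipopolysaccharide co-receptor gene Cd14 3.61-fold, with adjusted p of 0.00169 and 0.00144. The list was higher by a mean of 1.69 (camera adjusted p = 6.48e-07), and the adjusted p was 0.805 with an estimated correlation. Adjusted over the list alone, 19 members rose and 1 fell. The WT libraries differed among themselves in these genes: the WT list scores ran from -0.76 to 0.75, against 1.48 to 1.84 in KO.

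Fat-cell genes moved the other way. Of 18 adipocyte identity genes, 15 fell and 3 did not pass, with the same counts adjusted over the list alone. The hormone gene Retn, which encodes resistin, fell from 38100 ± 17200 to 2725 ± 1150 (log2 fold change -3.79, SE 0.40, adjusted p = 0.000939), and Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, from 4772 ± 1460 to 998.5 ± 198 (log2 fold change -2.23, SE 0.23, adjusted p = 0.000939). Pparg, the master transcription factor of adipocytes, fell with a log2 fold change of -0.97 (SE 0.18, adjusted p = 0.00486). Lep, which encodes leptin, fell with a log2 fold change of -1.11 (SE 0.33, adjusted p = 0.0307), a call that ended in 5 of the 7 fits without 1 library, with an adjusted p up to 0.112, and held without KO replicate 3 and without the WT column numbered 4. The list fell by a mean of 1.72 (camera adjusted p = 1.65e-07), and the adjusted p was 0.805 with an estimated correlation.

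Genes of lipid synthesis and of lipolysis fell together with these. Of 20 genes of fatty acid and triglyceride synthesis, 19 fell and 1 did not pass, and all 20 fell when adjusted over the list alone. Fasn, the fatty acid synthase, fell with a log2 fold change of -1.85 (SE 0.36, adjusted p = 0.00552), Dgat2, which makes triglyceride, with -1.67 (SE 0.24), Thrsp, a regulator of lipogenesis, with -2.47 (SE 0.35) and the malic enzyme Me1 with -1.27 (SE 0.17). The list's camera adjusted p was 2.38e-08, and the adjusted p was 0.805 with an estimated correlation. Of 21 genes of lipolysis and fatty acid oxidation, 12 fell and 1 rose (camera adjusted p = 0.00389, adjusted p = 0.805 with an estimated correlation). Adjusted over the list alone, 12 fell and 2 rose. Adrb3, the beta-adrenergic receptor of adipocytes, fell from 15830 ± 10900 to 1041 ± 243 (log2 fold change -3.71, SE 0.43, adjusted p = 0.0011), the hormone-sensitive lipase Lipe fell with a log2 fold change of -1.89 (SE 0.23) and the monoglyceride lipase Mgll with -1.26 (SE 0.17).

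Insulin signalling genes fell in 10 of 13 cases, among them the kinase Akt2 with a log2 fold change of -1.01 (SE 0.13, adjusted p = 0.00141) and the glycogen synthase Gys1 with -1.43 (SE 0.19, adjusted p = 0.00156). The same 10 fell when adjusted over the list alone, and the list had a camera adjusted p of 0.000316 and an adjusted p of 0.805 with an estimated correlation. Of 25 oxidative phosphorylation genes 9 fell (camera adjusted p = 0.00037, adjusted p = 0.805 with an estimated correlation), and the same number fell adjusted over the list alone. Among 19 genes of hypoxia and glycolysis, 5 fell and 4 rose (6 and 6 adjusted over the list alone). The falls included Pfkfb3, a regulator of glycolysis, at -1.57 (SE 0.20) and Bnip3, a mitophagy receptor, at -1.62 (SE 0.24). That list did not pass camera (adjusted p = 0.393, adjusted p = 0.805 with an estimated correlation), and it passed fry on the lower side (adjusted p = 0.0124), as did 7 fat lists in all.

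Endothelial genes fell in 15 of 18 cases, with the same count adjusted over the list alone, and the remaining 3 had log2 fold changes below 0 too. The list was lower by a mean of -0.95 (camera adjusted p = 1.37e-06), and the adjusted p was 0.805 with an estimated correlation. Mesothelial genes fell in 6 of 10 cases (9 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.805 with an estimated correlation), a list call that ended without the WT column numbered 4 (camera adjusted p = 0.0543). Extracellular matrix and fibroblast genes rose in 7 of 25 cases (7 adjusted over the list alone; camera adjusted p = 0.00389, adjusted p = 0.805 with an estimated correlation), and that call ended without the same library (camera adjusted p = 0.0833). They included the matrix metalloproteases Mmp2, at a log2 fold change of 1.92 (SE 0.24), and Mmp14, at 1.35 (SE 0.20). Cell cycle genes rose in 11 of 27 cases (21 adjusted over the list alone), and all 27 had log2 fold changes above 0 (camera adjusted p = 1.07e-05, adjusted p = 0.805 with an estimated correlation). The cell cycle list was higher by a mean of 1.01, and by 0.51 without the WT column numbered 4, which lay below the other WT columns at 0.54 and 0.47.

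Lymphoid and other immune genes were mixed. Cd8a, a marker of cytotoxic T cells, rose from 67.9 ± 32.9 to 150.8 ± 37.1 (log2 fold change 1.24, SE 0.38, adjusted p = 0.0346), a call that ended in 4 of the 7 fits without 1 library, those without KO replicate 1, 3 or 4 or the WT column numbered 1, with an adjusted p up to 0.0783. In the T cell list 4 of 20 members rose and none fell (2 rose adjusted over the list alone; camera adjusted p = 0.325). Foxp3, the transcription factor of regulatory T cells, averaged 20.5 ± 5.18 in KO and 19.4 ± 18.8 in WT (adjusted p = 0.587). Tnf, an inflammatory cytokine, rose with a log2 fold change of 1.48 (SE 0.45, adjusted p = 0.0331), a call that ended in 5 of the 7 fits without 1 library, with an adjusted p up to 0.0745, and held without the WT columns numbered 1 and 4. Without the WT column numbered 4 the log2 fold change of Tnf was 0.87. The B cell and macrophage inhibitory receptor gene Cd22 rose 4.45-fold, while Cd209a, a dendritic cell lectin, fell with a log2 fold change of -1.86 (SE 0.26) and the checkpoint receptor Lag3 with -1.44 (SE 0.18, adjusted p = 0.00132). Il1rl1, the receptor of interleukin-33 carried by regulatory T cells, type 2 lymphoid cells and mast cells, rose 2.11-fold (adjusted p = 0.00207). The list of mast cells, eosinophils and type 2 lymphoid cells had 6 of 12 members that rose and none that fell (7 rose adjusted over the list alone; camera adjusted p = 0.0472, adjusted p = 0.805 with an estimated correlation). That call ended without KO replicate 1, KO replicate 3 or the WT column numbered 1 (camera adjusted p = 0.0638, 0.118 and 0.145). In the interferon gamma response list 7 of 21 members fell and none rose (7 fell adjusted over the list alone; camera adjusted p = 0.0216, adjusted p = 0.807 with an estimated correlation), a call that ended without KO replicate 2 or the WT column numbered 3 (camera adjusted p = 0.054 and 0.121). Ifi27l2a, a type I interferon target, fell with a log2 fold change of -1.42 (SE 0.21), although that list did not pass camera (adjusted p = 0.393).

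The 10 largest rises among genes with a mean value of 50 or more were led by Hmga2 (chromosome 10, 120361275 to 120476469), an architectural chromatin protein, which averaged 523.3 ± 217 in KO and 18.5 ± 29.4 in WT (log2 fold change 6.18, SE 1.01, adjusted p = 0.00292). Prss46, Myh15, Serpinb1c, Fat3, Serpinb9b, Zranb3, Ereg, Vsig8 and Cd72 followed, with log2 fold changes from 5.11 down to 4.11. Zranb3, a DNA helicase, had the smallest adjusted p among them (0.000909), with 6543 ± 1050 in KO and 431.9 ± 343 in WT. Ereg encodes the growth factor epiregulin and Cd72 a receptor of B cells and myeloid cells. The 10 largest falls were Ear11, Prm2, Orm3, Serpina3b, Cyp2e1, Syt2, Mrgprg, Retn, Adrb3 and Rab9b. Cyp2e1, a cytochrome P450 of fat and liver, fell from 58280 ± 57100 to 1901 ± 479 (log2 fold change -4.49, SE 0.58, adjusted p = 0.00145), and Orm3, an acute-phase glycoprotein gene, from 340.8 ± 178 to 9.76 ± 3.37 (adjusted p = 0.000909). Prm2 is a sperm protamine gene whose reads in fat came from the WT libraries, with 328, 94 and 25 recovered reads there and 0 or 1 in each KO library. Ear11, Serpinb1c, Serpinb9b, Serpina3b and Orm3 belong to families of similar genes, so part of their reads may belong to a relative. Ucp1, the uncoupling protein of thermogenic fat, rose with a log2 fold change of 2.19 (SE 0.55, adjusted p = 0.016) at a level of only 18.5 ± 10.7 in KO and 2.85 ± 0.955 in WT. Npas2, a clock transcription factor, rose 2.77-fold.

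Several neighbours of Cd274 on chromosome 19 also differed in fat. Of 15 tested members of that list, 7 fell and 3 rose, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.119, adjusted p = 0.805 with an estimated correlation). It passed fry on the lower side (adjusted p = 0.0124) and for change in either direction (adjusted p = 9.8e-05). In fat 26 of the 35 lists passed that last test and 34.2% of all tested genes passed limma. Slc1a1 (28835049 to 28913960), a glutamate transporter, fell from 327.8 ± 154 to 34.0 ± 8.57, Ak3 (29020833 to 29047961), a mitochondrial adenylate kinase, with a log2 fold change of -1.10 (SE 0.12) and Ermp1 (29608214 to 29648415), a peptidase of the endoplasmic reticulum, with -1.10 (SE 0.12). The adjusted p values of limma were 0.00138, 0.00101 and 0.000982.

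The fat counts rest on limma with trend on log2(value + 1) over 7 libraries. Without the WT column numbered 3 the counts were 1575 higher and 1490 lower at the same threshold. The list calls compare a list's genes with other genes, and 20 of the 35 splits of the 7 libraries called as many lists as the real one, so chance cannot be excluded for the number of lists called. fry does not compare a list with other genes. Among the called lists it passed adipocyte identity (adjusted p = 0.00732), lipid synthesis (0.0124), insulin signalling (0.0206) and lipolysis (0.0206). It also passed lipid-associated macrophages (0.0251), endothelium (0.0302) and macrophages (0.0319). The called lists of cell cycle, oxidative phosphorylation, extracellular matrix, mesothelium, interferon gamma and mast cells did not pass fry (adjusted p = 0.126 to 0.25).

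**Figure D1:**
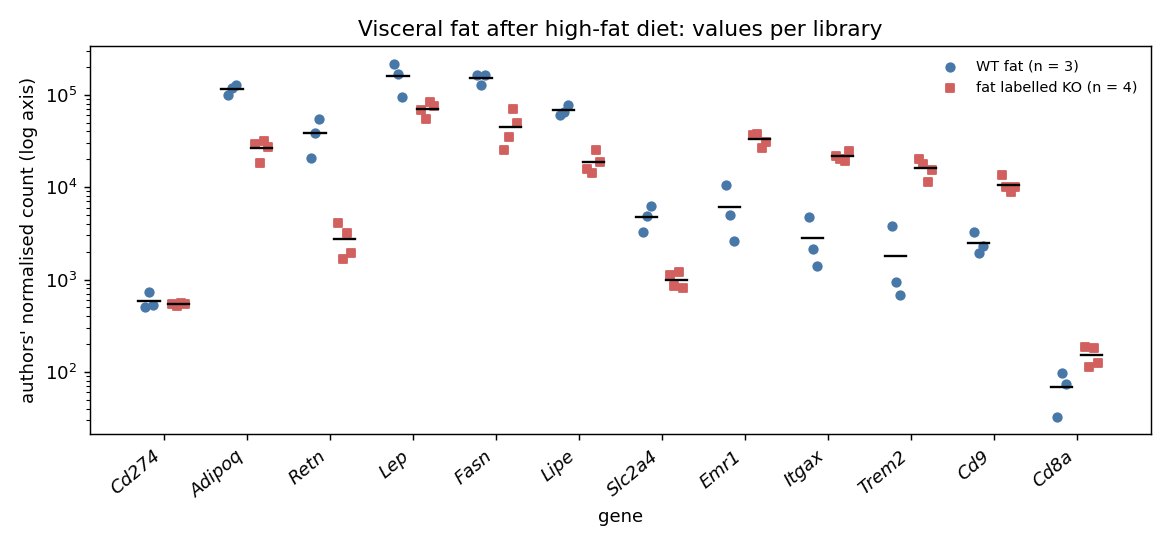
The authors' normalised counts of 12 genes in visceral fat on a log axis, with 1 point per library (circles for 3 WT libraries, squares for 4 libraries labelled KO) and a line at each group mean. The Cd274 values of both groups overlap, the KO values of Adipoq, Retn, Fasn, Lipe and Slc2a4 lie below all WT values, and those of Emr1, Itgax, Trem2 and Cd9 lie above them.

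In the tumours, no gene passed the threshold, and the genes of smallest p were targets of interferon gamma and genes of mast cells with higher averages in KO hosts. Iigp1 (chromosome 18, 60376027 to 60392634), an interferon-inducible GTPase, averaged 6352 ± 764 (SD, n = 3) normalised reads in KO hosts and 2978 ± 703 (SD, n = 3) in WT hosts. Cxcl9, a chemokine induced by interferon gamma that attracts T cells, averaged 5187 ± 859 and 2637 ± 384. Cpa3 (chromosome 3, 20215620 to 20242181), the carboxypeptidase of mast cells, averaged 1258 ± 716 in KO hosts and 225.3 ± 88.5 in WT hosts, and the mast cell tryptase genes Tpsb2 and Tpsab1 had folds of 6.04 and 6.42. These 5 genes had log2 fold changes of 1.09 (SE 0.17), 0.98 (SE 0.15), 2.48 (SE 0.39), 2.59 (SE 0.43) and 2.68 (SE 0.45), all with an adjusted p of 0.204 in edgeR. Tpsb2 and Tpsab1 are similar in sequence, so reads may have been exchanged between them.

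Of 13109 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p under 0.05, against 497 higher and 408 lower at an unadjusted p under 0.05. DESeq2 called 47 higher and 12 lower, and all 10 genes of smallest p in edgeR were among them. The 5 genes of smallest p on the lower side of edgeR, which did not pass there, were Arhgef37, Atf5, Dusp1, She and Ace. DESeq2 called Arhgef37, Atf5, Dusp1 and Ace lower (adjusted p = 0.0143, 0.00988, 0.00988 and 0.00471), and edgeR without a filter called Ace (adjusted p = 0.0483). Dusp1, a phosphatase induced early after stimulation, averaged 4205 ± 166 in KO hosts and 6598 ± 1330 in WT hosts (edgeR adjusted p = 0.354), and the stress-response transcription factor Atf5 averaged 1503 ± 163 and 2359 ± 316 (edgeR adjusted p = 0.354). Ace, the angiotensin-converting enzyme, averaged 629.9 ± 13.1 and 1308 ± 573 (edgeR adjusted p = 0.439). Its log2 fold change in edgeR was -1.05 with all libraries and -0.64 without WT-host replicate 2.

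As groups, the interferon gamma response, T cell, cytotoxic lymphocyte and mast cell lists ranked higher than other genes. Of 22 tested interferon gamma response genes, 19 had a log2 fold change above 0 and 0 passed over all genes, while 16 rose adjusted over the list alone. The list averaged 0.56 higher on the log2 scale (camera adjusted p = 4.04e-21), and the adjusted p was 0.423 with an estimated correlation. All 10 tested genes of mast cells, eosinophils and type 2 lymphoid cells had log2 fold changes above 0, with 6 rising adjusted over the list alone and a mean of 1.36 (camera adjusted p = 4.41e-11, adjusted p = 0.423 with an estimated correlation). Il1rl1, a member of the regulatory T cell list that is also carried by mast cells, averaged 362.6 ± 136 in KO hosts and 118.3 ± 43 in WT hosts. It did not pass edgeR (adjusted p = 0.263) and passed DESeq2 (adjusted p = 0.000502) and edgeR without a filter (adjusted p = 0.0158). The 3 KO-host scores lay above the 3 WT-host scores in both lists, for which the exact permutation p was 0.1, the smallest possible.

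Of 20 T cell genes, 19 had log2 fold changes above 0 and 8 rose adjusted over the list alone, with a mean of 0.56 (camera adjusted p = 8.24e-12, adjusted p = 0.423 with an estimated correlation). The T cell list scores of the hosts overlapped (exact permutation p = 0.2), and KO-host replicate 2 stood apart at 1.07 against 0.22 and 0.39 in the other KO hosts. Without KO-host replicate 2 the T cell list was 0.31 higher, and Cd8a had a log2 fold change of 0.57. Cd8a averaged 1691 ± 785 in KO hosts and 838.9 ± 254 in WT hosts (log2 fold change 1.01, SE 0.29, adjusted p = 0.541), whereas Cd4, the marker of helper T cells, averaged 496.8 ± 107 and 545.8 ± 51 (adjusted p = 0.904). The T cell kinase gene Zap70 averaged 609 ± 120 and 370.3 ± 62.5 (adjusted p = 0.511). Of 20 cytotoxic lymphocyte genes 18 were above 0 and none rose adjusted over the list alone (camera adjusted p = 7.4e-08, adjusted p = 0.423 with an estimated correlation), and the list mean of 0.44 was 0.18 without KO-host replicate 2. Prf1, which encodes perforin, averaged 1550 ± 335 and 887.5 ± 281 (adjusted p = 0.511), Ifng 537.6 ± 287 and 271 ± 97.4 (adjusted p = 0.646) and Gzmb, which encodes granzyme B, 3034 ± 430 and 2514 ± 171 (adjusted p = 0.745). Ifng had a log2 fold change of 0.98 with all libraries and of 0.46 without KO-host replicate 2. Among 14 immune checkpoint genes other than Cd274, 12 were above 0 and 6 rose adjusted over the list alone (camera adjusted p = 2.65e-07, adjusted p = 0.423 with an estimated correlation), and the list mean of 0.49 was 0.32 without KO-host replicate 2. Pdcd1, the gene of PD-1, averaged 1077 ± 468 in KO hosts and 418 ± 137 in WT hosts (log2 fold change 1.36, SE 0.29, edgeR adjusted p = 0.354). Cd96, a receptor of T and natural killer cells, averaged 320.2 ± 67.6 and 138.1 ± 24.7 (edgeR adjusted p = 0.245). Both were called higher by DESeq2 (adjusted p = 0.000669 and 0.00142) and by edgeR without a filter (adjusted p = 0.0228 and 0.0338). DESeq2 also called Prf1 (adjusted p = 0.049), but not Zap70, Ifng, Cd8a, Gzmb or Cd4 (adjusted p = 0.086 to 0.958). Foxp3 averaged 268.8 ± 54.3 and 216.3 ± 87.2 (adjusted p = 0.855), and the regulatory T cell list passed camera on the higher side (adjusted p = 0.0326, adjusted p = 0.557 with an estimated correlation), a call that ended without KO-host replicate 2 or WT-host replicate 1 (camera adjusted p = 0.637 and 0.202).

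Among myeloid and presenting-cell genes, the macrophage list averaged 0.23 higher (15 of 21 genes above 0, camera adjusted p = 0.000146, adjusted p = 0.423 with an estimated correlation). Without KO-host replicate 1 the macrophage list was 0.038 higher (camera adjusted p = 0.134), and without WT-host replicate 2 it was 0.11 higher. The scavenger receptor gene Msr1 averaged 4163 ± 867 in KO hosts and 2831 ± 82.9 in WT hosts (adjusted p = 0.511). The lists of MHC class I and class II presentation passed camera on the higher side (adjusted p = 0.0146 and 0.0117, both with an adjusted p of 0.522 with an estimated correlation). So did the inflammatory cytokines (adjusted p = 0.0326, adjusted p = 0.643 with an estimated correlation) and the cell cycle genes (adjusted p = 0.000925, adjusted p = 0.522 with an estimated correlation). These calls ended without 1 library: MHC class I without KO-host replicate 1 or 2 or WT-host replicate 3 (camera adjusted p up to 0.229), MHC class II without KO-host replicate 1 or 2 or WT-host replicate 2 or 3 (up to 0.12), the inflammatory cytokines without KO-host replicate 2 or WT-host replicate 2 or 3 (up to 0.458) and the cell cycle without WT-host replicate 2 (0.0782). Xcr1, the receptor of cross-presenting dendritic cells, averaged 97.5 ± 23 and 27.0 ± 5.3 (edgeR adjusted p = 0.245). Ccr7, the receptor of dendritic cells that migrate to lymph nodes, averaged 328.7 ± 47.7 and 516.9 ± 29.6 (edgeR adjusted p = 0.455). DESeq2 called Xcr1 higher (adjusted p = 0.00371) and did not call Ccr7 (adjusted p = 0.0695). The lists of dendritic cells and of extracellular matrix passed the fry test for change in either direction (adjusted p = 0.00307 for both) and not camera (adjusted p = 0.421 and 0.648). Postn, a matrix protein gene, averaged 574 ± 70.7 and 306.1 ± 18.4 (edgeR adjusted p = 0.204), and the fibronectin gene Fn1 averaged 1569 ± 423 and 2211 ± 396 (edgeR adjusted p = 0.676). DESeq2 called Postn higher (adjusted p = 0.000959) and did not call Fn1 (adjusted p = 0.394). Mki67, a proliferation marker, averaged 2974 ± 206 and 2621 ± 612 (adjusted p = 0.855), and Krt18, an epithelial keratin of the carcinoma, 68.2 ± 27.5 and 83.3 ± 23.9 (adjusted p = 0.897).

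Other lists ranked lower in KO hosts. Skeletal muscle genes averaged -0.90 on the log2 scale (11 of 12 below 0, camera adjusted p = 3.11e-05, adjusted p = 0.423 with an estimated correlation; -0.57 without WT-host replicate 3), at a low level, with the myoglobin gene Mb at a log2 fold change of -1.32 (SE 0.46, adjusted p = 0.646). Type I interferon response genes averaged -0.26 (22 of 27 below 0, camera adjusted p = 0.000332, adjusted p = 0.6 with an estimated correlation), with Rsad2, which encodes viperin, at 4074 ± 1100 and 6701 ± 2700 (adjusted p = 0.676). The mean of that list was -0.085 without WT-host replicate 2 and -0.51 without WT-host replicate 3. B and plasma cell genes averaged -0.41 (10 of 11 below 0, camera adjusted p = 0.00941, adjusted p = 0.423 with an estimated correlation). Endothelial genes averaged -0.38 (14 of 16 below 0, camera adjusted p = 0.00615, adjusted p = 0.423 with an estimated correlation), with the vascular growth factor receptor gene Kdr at a log2 fold change of -0.94 (SE 0.30, adjusted p = 0.596). Immediate early genes (adjusted p = 0.000389), heat shock and unfolded protein response genes (adjusted p = 0.000511), oxidative phosphorylation genes (adjusted p = 0.00125) and hypoxia and glycolysis genes (adjusted p = 0.00253) passed camera on the lower side too. With an estimated correlation, their adjusted p values were 0.423, 0.423, 0.6 and 0.6. Calls on the lower side ended for the type I interferon response without KO-host replicate 3 or WT-host replicate 2 (camera adjusted p = 0.051 and 0.454), for B and plasma cells without KO-host replicate 1 or WT-host replicate 3 (0.178 and 0.0585) and for endothelium without KO-host replicate 2 (0.0548). They ended for oxidative phosphorylation without KO-host or WT-host replicate 1 (camera adjusted p = 0.062 and 0.451) and for hypoxia and glycolysis without KO-host or WT-host replicate 2 (0.339 and 0.361). Hspa1b, a heat shock protein gene nearly identical to Hspa1a and therefore uncertain, had a log2 fold change of -1.12 (SE 0.34, adjusted p = 0.552).

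The tumour counts depended on the fit: without KO-host replicate 3 edgeR called 9 genes higher, without WT-host replicate 3 it called 10 higher and 11 lower, and without a filter on low counts it called 21 higher and 1 lower. No list passed fry's test for movement in a single direction, and 11 of the 19 list calls ended without at least 1 of the 6 libraries while 8 held without each, those of interferon gamma, T cells, mast cells, cytotoxic lymphocytes, checkpoints, muscle, immediate early genes and heat shock.

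**Figure D2:**
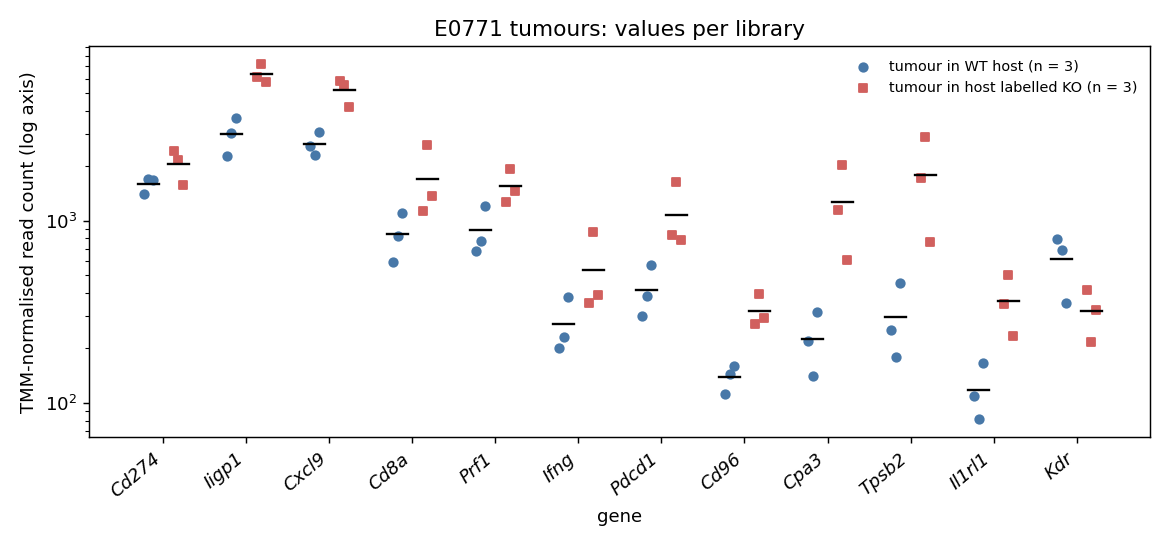
TMM-normalised read counts of 12 genes in the tumours on a log axis, with 1 point per library (circles for 3 tumours in WT hosts, squares for 3 tumours in KO hosts) and a line at each group mean. Iigp1, Cxcl9, Pdcd1, Cpa3, Tpsb2 and Il1rl1 have all KO-host values above all WT-host values, while those of Cd274 and Ifng overlap.

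Across tissues, no relation between the KO effect in fat and the KO effect in the tumours passed its test. Over 12529 genes tested in both, Spearman's rho of the log2 fold changes was 0.14 and Pearson's r 0.15, and the exact permutation p of rho over 700 relabellings of the libraries was 0.383. This correlation is across genes, which are not independent replicates. The lipid-associated macrophage list was 2.41 higher in KO fat and 0.04 higher in the tumours of KO hosts. The interferon gamma response list had opposite signs, -0.58 in fat (-0.27 without the WT column numbered 3) and 0.56 in the tumours. The exact permutation p values of these differences were 0.0171 and 0.0186. The relabelling assumes no KO effect in either tissue, so an effect in 1 tissue alone can make such a p small, and equal effects in both were not tested. The smallest exact permutation p was 0.00714, for the mesenchymal transition list (0.30 in fat, -0.17 in the tumours). Adjusted over the 34 lists tested in both tissues, the smallest of these p was 0.158, so no difference between tissues passed. Among the 5 genes named in both tissues (Cd274, Il1rl1, Trem2, Cd8a and Foxp3) no difference passed either, and the smallest adjusted p was 0.221, for Trem2. The tissues came in separately processed tables, so only fold changes within a table were compared. They also carry the transcripts of different sexes, with 3272 to 7052 recovered reads of the Y-linked gene Ddx3y in fat and 0 to 8 reads in the tumours. Sex therefore cannot be separated from tissue in this comparison.

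**Figure D3:**
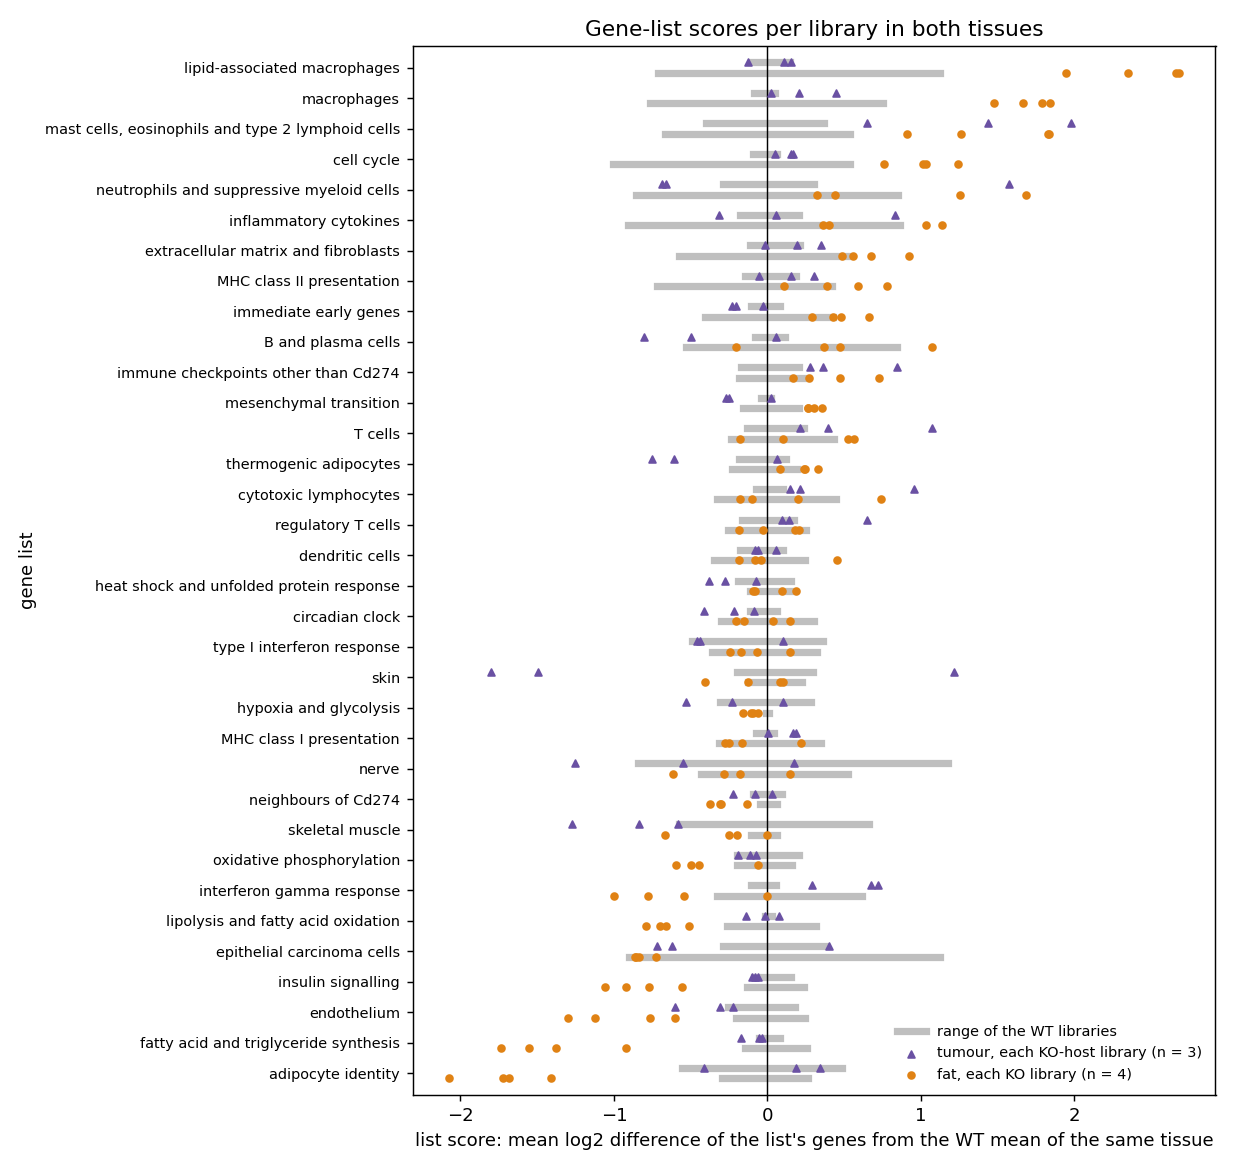
Scores of 34 gene lists per library in both tissues, as the mean log2 difference of a list's genes from the WT mean of the same tissue. Triangles are the 3 KO-host tumours, circles the 4 KO fat libraries and grey bars the range of the 3 WT libraries of the tissue. The lipid-associated macrophage scores of KO fat lie between 1.95 and 2.68, the adipocyte identity scores between -2.07 and -1.41, and the mast cell list lies above the WT range in both tissues.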

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

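The splits of the libraries and the thinning of reads were planned before their results were seen, and the other tests in this part were chosen only after the result they weigh was seen. Chance marks about 1 in 20 groups of 4 values by Dixon's test, and 4 of 92 sets of values tested (4.35%) had a library far from the other 3 in KO fat. Serpinb9b was 5640 in KO replicate 1 against 483.9 to 1213 in the other KO libraries, which also lay above the WT values (mean 89.8, highest 197.9). Prm2 had 0 recovered reads in KO replicate 1 and 1 in each other KO library, a difference at the floor. Cd209a was 109.9 in KO replicate 3 (KO mean 163.2) and Tnf was 150.1 in KO replicate 1 (KO mean 126.3). Serpinb9b averaged 1986 ± 2460 in KO, a mean that rests on that library.

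For the number of genes called in fat the splits argue against chance: 1 of the 35 splits of the 7 fat libraries, the real one, gave 4947 genes, and the highest of the others gave 0. A share of 1 in 35 is the smallest possible. The splits do not separate the KO label from other differences between the groups. For the number of lists called in fat chance cannot be excluded: 20 of the 35 splits called as many as the real 13, and the highest other called 22. In the tumours the 10 splits are too few for a share under 0.05. The real split called 19 lists and the highest other 17, with 1 of 10 splits as high, and 0 genes against 1, with 10 of 10 splits as high.

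In the fat labelled KO the macrophage lists ranked higher and the adipocyte identity list lower, each with an adjusted p of 0.805 with an estimated correlation. A lower share of adipocytes alone would raise the transcripts of every other cell type, but the endothelium list lay below the macrophage list by -2.64 on the log2 scale (SE 0.55) and was lower in KO itself. These values bear on a lower share of adipocytes alone. Other changes in the mix of cells, a larger share of macrophages among them, were not tested and stay open. No library lay among those of the other group. The gap was 0.82 between the lowest KO and the highest WT library in the lipid-associated macrophage list. It was 1.11 between the lowest WT and the highest KO library in the adipocyte identity list. These lists made the pattern, so the gaps restate it and cannot decide whether libraries were exchanged between the groups. A difference in depth is argued against by the value of 2.41 for the lipid-associated macrophage list after all libraries were thinned to 29362788 reads. The KO label itself and differences in body weight, age, litter, fat depot or sampling site, which the labels do not give, stay open and untested. Reads of other organs differed between the fat libraries: Prm2 had 328, 94 and 25 recovered reads in the WT columns and 0 or 1 in each KO library. Pnlip had 489 in KO replicate 4. The Prm2 reads separated the groups (limma adjusted p = 0.00161), while the Pnlip reads came mostly from that KO library. Whether a difference in sampling made them, or altered other genes, cannot be told from these reads.

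Cd274 was not lower in the fat labelled KO. The difference between Cd274 and the adipocyte identity list was 1.63 (SE 0.24). Any unchanged gene would give such a value while that list fell, so it cannot tell whether most Cd274 reads came from cells other than adipocytes. Whether the reads come from exons outside the deleted part cannot be told apart from an intact gene, since the whole-gene log2 fold change of -0.10 holds no value per exon. A wrong group label for all libraries cannot be excluded by these values either.

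In tumours of KO hosts the interferon gamma, T cell and mast cell lists ranked higher, each with an adjusted p of 0.423 with an estimated correlation. Lymph node in the samples is argued against by the B and plasma cell list, which lay below the T cell list by -0.97 (SE 0.15). Dilution of the WT-host tumours by muscle is argued against by the skeletal muscle list, which took at most 0.00353% of reads where 32.4% would be needed. Library quality cannot be told apart from the host, since reads outside genes took 17.2% to 19.9% of reads placed once in KO hosts and 20.4% to 22.7% in WT hosts, and within hosts the mean of the 3 list scores had a slope of -0.17 per percentage point (SE 0.11, exact permutation p = 0.25 over 36 relabellings) where -0.25 would make the whole difference. The KO label itself and differences in tumour size or sampling site stay open and untested.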

How the results depend on the processing

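The alternatives were planned except edgeR on recovered reads and the fat replicate block by column number, which were chosen after seeing the data. In the tumours DESeq2 called 47 genes higher and 12 lower and edgeR without a filter 21 and 1, where edgeR called 0 and 0 (497 and 408 at an unadjusted p under 0.05). Of 46 named tumour genes 16 passed in DESeq2. Leaving out each library gave 0 to 10 genes higher and 0 to 11 lower, 15 to 20 lists called and a Cd274 log2 fold change of 0.22 to 0.53. With the replicate block, edgeR called 0 higher and 0 lower and camera 19 lists. The tumour numbers share only a number: 0 of 6 libraries correlated best with the library of their own number, and 0 of 3 pairs had a correlation over 0.1. In fat the planned replicate block could not use the labels' numbers, which do not match the WT columns, so the column numbers 1, 3 and 4 shared by both groups were used. With that replicate block limma called 1460 higher and 1460 lower and camera 15 lists, Cd274 was at -0.076, and the adjusted p of Lep, Ucp1, Cd8a and Tnf was 0.116, 0.0687, 0.059 and 0.0509. The fat columns share only a number too: 2 of 6 libraries correlated best with their own number, and 1 of 3 pairs had a correlation over 0.1. With a correlation estimated for each list, 0 tumour lists and 0 fat lists were called, and fry called 0 tumour lists and 9 fat lists. Of those 9, camera with the preset correlation had called 7 too. fry tests whether the genes of a list moved, not whether they moved more than other genes. The correlations were estimated from the data. An estimate above the preset correlation widens the test of a list. Estimates of the called lists all lay above it, at 0.0562 to 0.8 in the tumours and 0.204 to 0.863 in fat. Some lists not called lay below it, such as thermogenic adipocytes in the tumours (-0.031) and hypoxia and glycolysis in fat (-0.037). With the preset correlation, splits other than the real one called up to 17 tumour lists and 22 fat lists. For the other changes named here the cause was not tested. The signs of median, mean and test differed for the tumour lists of skin, extracellular matrix, neighbours of Cd274 and lipolysis and for regulatory T cells in fat, of which none was called.

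In fat, leaving out each library gave 1575 to 2691 genes higher, 1490 to 2567 lower, 12 to 16 lists called and a Cd274 log2 fold change of -0.20 to 0.076, which was 0.076 without the WT column numbered 3. Of the 4947 genes called, 2874 to 4937 were called again with the same sign over all 16 alternatives and 0 with the opposite sign. Of 13 lists called 9 kept their call without each library, and in the tumours 8 of 19. Spearman's rho across tissues was 0.0941 to 0.168 without each library. Signs turned for tumour Cd4 (-0.26 to 0.022, above 0 without KO-host replicate 1), fat Foxp3 (-0.051 to 1.16, below 0 without the WT column numbered 1) and the tumour inflammatory cytokine list (-0.13 to 0.44, below 0 without KO-host replicate 2), none of which passed in those fits. With the fat reads thinned to the same total of gene reads, 2436 genes were called higher and 2478 lower, and whether depth limits single low genes was not tested.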

Other observations

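The joint test of the mast cell list was chosen after the values were seen, while the lists were fixed earlier. Of the immune checkpoint list in fat, 4 members rose and 1 fell (4 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.257, adjusted p = 0.807 with an estimated correlation). Havcr2, the gene of the inhibitory receptor TIM-3, chosen after its values were seen, rose from 135.1 ± 82 to 608.5 ± 111 (limma adjusted p = 0.00369), whereas Lag3 fell from 325.2 ± 26.4 to 120.1 ± 18.9. Il33, a neighbour of Cd274 that encodes the ligand of the receptor made by Il1rl1, was also chosen after its values were seen and rose from 521.9 ± 147 to 1283 ± 254 (limma adjusted p = 0.00291).

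Some libraries held reads of other organs. Prm1, Tnp1 and Tnp2, genes of sperm development, had 86, 115 and 119 recovered reads in the WT fat column numbered 1, 3 to 52 in the other WT columns and 0 or 1 in each KO fat library. Pnlip, Cela2a, Ctrb1 and Cpa1, enzymes of the exocrine pancreas, had 489, 448, 366 and 306 recovered reads in KO fat replicate 4 and 0 to 11 in each other fat library. The Y-linked gene Ddx3y had 3272 to 7052 recovered reads in the fat libraries and 0 to 8 reads in the tumours, and Xist had 1 to 50 in fat and 933 to 2846 in the tumours, so the tissues carry the transcripts of different sexes.

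The list of mast cells, eosinophils and type 2 lymphoid cells was higher in the KO libraries of both tissues, by 1.46 in fat and 1.36 in the tumours. In fat 8 of its 12 members lay above 0 and 4 below, those of Kit, Gata2, Gata3 and Rora, and its camera call ended in 3 of the 7 fits without 1 library. A rise of mast cell transcripts with the KO label in both tissues may be a shared effect, as a hypothesis. Over 700 relabellings of both tissues the exact permutation p of a difference as large in both was 0.00286, and 0.0971 after adjustment over the 34 lists tested in both, so the hypothesis stays open. These relabellings assume no effect in either tissue, so a strong effect in 1 tissue can make this p small. For the 5 genes named in both tissues the same test, also chosen after the values were seen, gave adjusted p values of 0.0143 for Il1rl1, 0.0179 for Cd8a, 0.0571 for Trem2, 0.112 for Foxp3 and 1 for Cd274, which had opposite signs. Il1rl1 and Trem2 had been named for small p values in each tissue, so their p values are too small. Since the relabelling assumes no effect in either tissue, none of these p values, that of Cd8a included, tests a rise in both. In the tumours neither Il1rl1 nor Cd8a passed edgeR, while Il1rl1 passed DESeq2 (adjusted p = 0.000502) and edgeR without a filter (adjusted p = 0.0158).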
